A study of Homo sapiens with 6 samples.

How the data were processed

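RNA-seq of polyadenylated RNA was analysed in 6 ARPE-19 libraries, 3 exposed to 600 µM H2O2 for 24 h and 3 exposed likewise after 24 h with 100 µM arbutin. Per the labels' protocols, total RNA was extracted with a phenol-based reagent and libraries were made with Illumina kits. Per the submitters' processing notes, cutadapt 1.9 and FastQC were used and the genome build was GRCh38, also called hg38. The aligner, the counting tool, the annotation release and whether strand was used are not given in the sources used here, so antisense and overlapping genes cannot be separated. The deposited table holds 36717 genes, and per the file headers it gives whole-number counts and FPKM values (scaled to gene length and library total) in each library, made by the authors; the lengths and totals behind the FPKM values are not given in the sources used here. The deposited counts are whole numbers whose totals, 68953117 to 74178269, differ between libraries, and were taken as not normalised. The gene length implied by the ratio of count to FPKM varied between libraries with a median CV of 0.47% over 14271 genes with more than 50 counts in all libraries. Coordinates and symbols are those of the file. Of its gene identifiers 96.8% were found in GENCODE 29, of which 62.1% had the same start and end, so the file rests on another release.

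Raw counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided, group as the only term) with Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. The filter kept 21059 genes, and the genes left out held 0.0566% of the counts. CPM values use TMM-scaled totals and are given as mean ± SD of 3 libraries, and the error of a log2 fold change is its SE, the change divided by the root of the F statistic. The common biological coefficient of variation was 16.8%. The depth gives about 70 counts per CPM unit, so genes under 1 CPM rest on few counts. Where a group had 0 counts, a fold, called its bound, was computed against 3 counts over the group, without counting error. The interval of a ratio of counts covers counting error only, at 95%. Bootstrap intervals, also at 95%, resample the genes of a set as if independent. The fixed design named limma on log2(FPKM + 1), with FPKM of at least 1 in 3 libraries, unless the table also held counts; it did, so that fit is an alternative.

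Gene lists (33, with 829 of their 856 entries found in the table) were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01, for lists of at least 5 tested genes, and again with an estimated correlation and with fry. Genes of the lists missing from the table are not analysed here. GO, KEGG and Reactome terms named in the file were tested in the same way for terms of 10 to 300 tested genes, against genes with a term of the same kind. Part of the GO entries of 2268 genes and of the KEGG entries of 6 genes is not used here. The lists, the tests and the alternatives were fixed before the data were examined. So was the rule for named genes: (a) the 10 largest log2 fold changes in each direction among called genes whose groups do not overlap and that have a gene symbol; (b) up to 4 members of each list with the smallest p among those past the test, else past it over the list alone, else the single smallest; (c) 27 readout genes. Camera with the trend on gene length or GC content removed was added after the data were seen. So were the 8 largest changes per direction at a mean of at least 10 CPM, members behind any count of 5 or fewer, 3 members per described term, and the mitochondrial and 5.8S ribosomal RNAs.

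Alternatives were DESeq2 1.42.0, its size factors in edgeR, median scaling, no low-count filter, FPKM of at least 5 in 3 libraries, protein-coding genes, a replicate block, each library left out in turn, other thresholds, and limma on log2(FPKM + 1) also with a pseudocount of 0.1, quantile normalisation, no variance trend or array weights. The FPKM-specific alternatives were changed within the limma fit. Two-sided tests were used throughout. The procedure was tested on simulated counts for the 21059 genes of this comparison, with 200 genes and 1 further list changed. It recovered 28% of genes changed by 1.25-fold, 70% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, with 5 false calls among 162. It passed the changed list and 0 of 30 unchanged lists. Simulated genes were drawn independently, so this does not bear on lists of correlated genes. Far fewer genes were changed than the 29.8% called in the data, so the recovery may differ there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main test. Some genes that the naming rule selects are not reported here by name, and they remain in the counts.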

Results

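Polyadenylated RNA was sequenced from ARPE-19 cells, an established human cell line derived from the retinal pigment epithelium, the pigmented layer that supports the photoreceptors. Cells of the arbutin group were kept for 24 h with 100 µM arbutin, a plant-derived glucoside of hydroquinone, and were then exposed to 600 µM hydrogen peroxide (H2O2) for 24 h. Cells of the H2O2 group received the same exposure after 24 h without arbutin. Each group had 3 libraries. The labels do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. No untreated cells were analysed here, so every value compares arbutin plus H2O2 with H2O2 alone. The counts over all genes summed to 73752946, 69607125 and 68953117 in H2O2 replicates 1 to 3 and to 73520544, 74178269 and 69959208 in arbutin replicates 1 to 3. Within a group, pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of 11.2 to 20.6, so none was counted as a copy of another.

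The groups separated on the first principal component, which held 32.3% of the variance. The arbutin libraries lay at 41.9, 39.7 and 39.0 and the H2O2 libraries at -50.7, -44.2 and -25.8. H2O2 replicate 3 stood apart from the other libraries on the second component, at 63.5. The 2 mitochondrial ribosomal RNAs took 2.73% ± 0.281 of all counts in the H2O2 group and 4.19% ± 0.289 in the arbutin group (SD, n = 3).

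**Figure D1:**
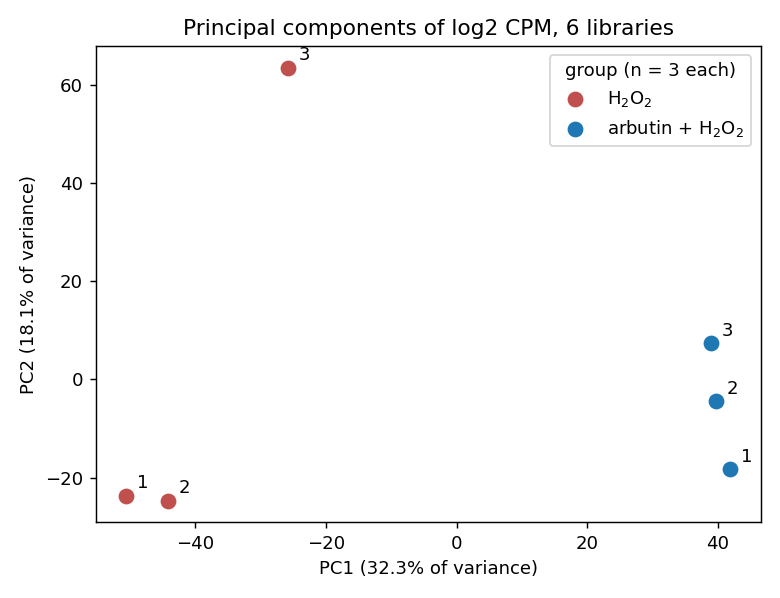
Principal components of log2 CPM for the 6 libraries, with the first component on the x axis (32.3% of the variance) and the second on the y axis (18.1%). Points are libraries coloured by group and numbered by replicate; the arbutin libraries lie between 39.0 and 41.9 on the first component, and H2O2 replicate 3 lies at 63.5 on the second.

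The comparison asks which transcripts differ in H2O2-exposed cells when arbutin was given beforehand, in a study whose title names the mitogen-activated protein kinase (MAPK) pathway. Pretreated cells had lower levels of immediate early genes, mitotic genes, cholesterol synthesis genes and heat shock genes. They had higher levels of genes regulated by the antioxidant transcription factor NRF2 and of genes of the integrated stress response. Of 21059 genes tested, 3035 were higher and 3232 lower with arbutin by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, which is 29.8% of the genes. Most differences were small: the median absolute log2 fold change of the called genes was 0.37, and 221 genes were higher and 234 lower by at least 2-fold. The 3 values of one group lay wholly above those of the other for 44.6% of the tested genes, where chance gives 10%. Without H2O2 replicate 2 the number of lower genes was 2150, and without H2O2 replicate 3, which stood apart, 2970 genes were higher and 3018 lower, with 15 lists and 207 annotated terms past camera.

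FOS, which encodes a subunit of the AP-1 transcription factor (ENSG00000170345, GRCh38 chromosome 14, 75278826 to 75282230, plus strand), fell from 80.0 ± 8.11 to 19.9 ± 1.49 CPM (the standard library-scaled count unit; SD, n = 3 per group), a log2 fold change of -2.01 ± 0.0822 (SE; edgeR adjusted p = 1.07e-06). It was among 21 of the 25 tested immediate early genes, transcribed within minutes of a stimulus, that were lower with arbutin. EGR1 fell from 98.1 ± 11.3 to 29.7 ± 1.32 CPM, ARC from 137 ± 8.80 to 56.6 ± 1.73 CPM and ATF3 from 296 ± 5.44 to 158 ± 3.77 CPM. JUN, the partner of FOS in AP-1, had a log2 fold change of -0.54. NR4A1, CCN1 and MCL1 were higher, with log2 fold changes of 0.42, 0.44 and 0.14. SRF, with a log2 fold change of 0.14, did not pass (adjusted p = 0.0518), but passed in 7 of 18 alternatives (0.0157 to 0.186 over all), among them that without H2O2 replicate 3. MCL1 lost its call without H2O2 replicate 1, H2O2 replicate 2 or arbutin replicate 2 (edgeR adjusted p = 0.0994, 0.101 and 0.0633). Adjusted over the list alone, 21 genes were lower and 4 higher. The list's median log2 fold change was -0.60, and it differed from other genes by camera (adjusted p = 7.48e-27, and 0.0455 with an estimated correlation).

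**Figure D2:**
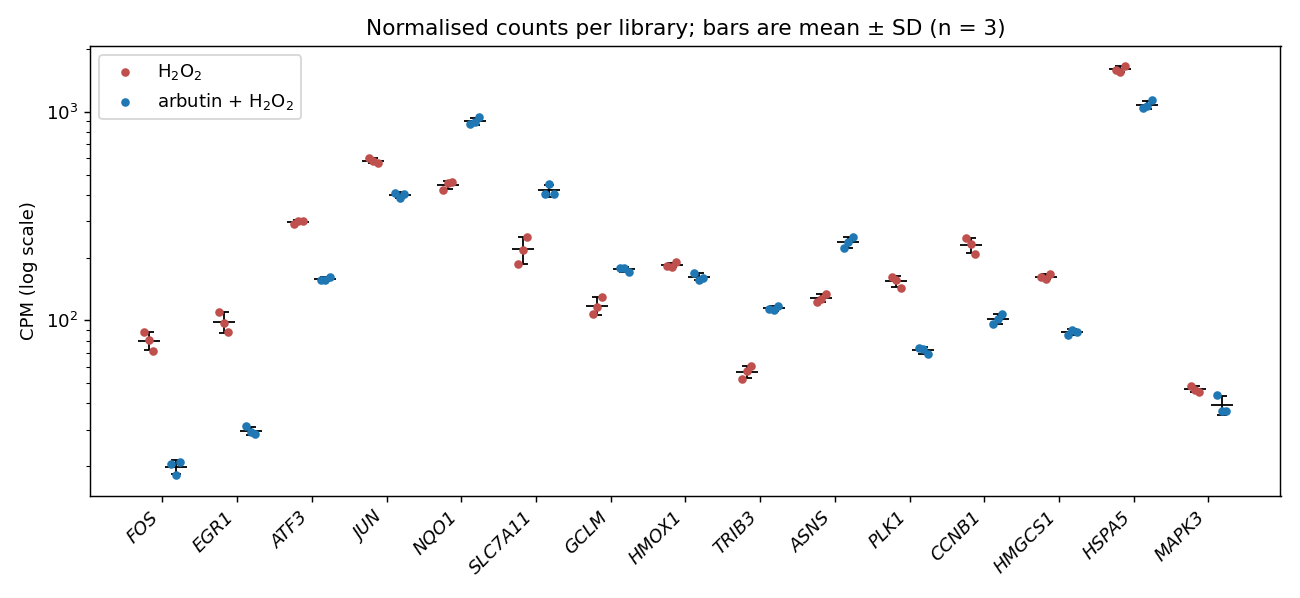
Normalised counts (CPM) on a log scale (y axis) for 15 genes named in the text (x axis), in each of the 3 H2O2 libraries and the 3 arbutin plus H2O2 libraries. Points are libraries and the black bars give the mean and SD of each group; FOS fell from a mean of 80.0 to 19.9 CPM and NQO1 rose from 447 to 903 CPM.

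Among the genes of the MAPK cascades themselves, changes were small and went both ways. Of 39 kinase genes, 13 were higher and 8 lower, and the list did not pass camera (median log2 fold change 0.04, adjusted p = 0.261). BRAF and MKNK2 rose, with log2 fold changes of 0.50 and 0.43. MAPK8, which encodes JNK1, had a log2 fold change of 0.29. MAPK3, which encodes ERK1, had a log2 fold change of -0.26 (adjusted p = 0.0198). Its call was lost without H2O2 replicate 1, H2O2 replicate 2, arbutin replicate 2 or arbutin replicate 3 (edgeR adjusted p = 0.0786, 0.0545, 0.0916 and 0.0736). MAPK14, which encodes p38 alpha, did not pass (log2 fold change -0.15, adjusted p = 0.0628), but passed in 5 of 18 alternatives (adjusted p = 0.0359 to 0.18 over all), among them that without arbutin replicate 2 (edgeR adjusted p = 0.0464). Adjusted over the list alone, 14 kinase genes were higher and 10 lower. These are transcript levels, and kinase activity was not measured.

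Of 25 genes of the MAPK transcriptional output, which report ERK signalling through their expression, 11 were lower and 5 higher, the same counts as adjusted over the list alone. EMP1, PHLDA1 and DUSP8 fell, with log2 fold changes of -0.52, -0.43 and -0.42, and DUSP6, a phosphatase that acts on ERK, fell by 0.38. The 5 higher genes were CCND1, from 738 ± 52.9 to 970 ± 15.8 CPM, SPRED2, ETV5, FOSL1 and MYC, with log2 fold changes of 0.39, 0.29, 0.23, 0.28 and 0.14. The list's median was -0.14 and its camera adjusted p was 0.0621. The list passed without H2O2 replicate 2 (camera adjusted p = 0.0175), without arbutin replicate 1 (0.0204) and without the low-count filter (0.0137). DUSP1 had a log2 fold change of -0.14 and lost its call without H2O2 replicate 1, H2O2 replicate 2 or arbutin replicate 3 (edgeR adjusted p = 0.101, 0.0509 and 0.0884). FOSL1 lost its call without H2O2 replicate 1 (0.0585), and MYC without any library except arbutin replicate 3 (0.0724 to 0.116).

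NQO1, a quinone reductase and standard NRF2 target (ENSG00000181019, GRCh38 chromosome 16, 69706996 to 69726668, minus strand), rose from 447 ± 20.4 to 903 ± 34.8 CPM, a log2 fold change of 1.01 ± 0.0463 (SE, n = 3; edgeR adjusted p = 1.07e-06). Of 30 NRF2 targets, 23 were higher and 1 lower, and adjusted over the list alone 23 were higher and 2 lower. TXNRD1, thioredoxin reductase, rose from 2128 ± 121 to 3276 ± 78.3 CPM. ME1, which supplies NADPH, had a log2 fold change of 0.69. SLC7A11, the cystine importer, had one of 0.94, and GCLM, which takes part in glutathione synthesis, of 0.58. HMOX1, heme oxygenase 1, was the lower member, falling from 184 ± 4.85 to 162 ± 6.41 CPM, a call lost with quantile-normalised values (limma adjusted p = 0.066). The list passed camera (median 0.42, adjusted p = 3.60e-17, and 0.0455 with an estimated correlation).

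Of 27 tested genes in a separate list of antioxidant enzymes, which also holds glutathione transferases and enzymes that reduce oxidised proteins, 14 were lower and 2 higher (16 lower and 2 higher adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.000827; adjusted p = 0.371 with an estimated correlation). CAT, catalase, fell from 83.1 ± 3.62 to 66.6 ± 2.15 CPM. GPX1 and PRDX3, a cytosolic and a mitochondrial peroxidase, and NNT had log2 fold changes of -0.34, -0.35 and -0.34. The higher members were MGST1 (0.27) and SOD2 (0.22), the mitochondrial superoxide dismutase. The call was also lost with FPKM of at least 5 required in 3 libraries (camera adjusted p = 0.104).

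Of 30 genes of the integrated stress response, 24 were higher and 1 lower (25 and 2 adjusted over the list alone). TRIB3, a pseudokinase induced by ATF4, rose from 56.8 ± 3.98 to 114 ± 3.13 CPM, and ASNS, asparagine synthetase, from 128 ± 6.07 to 236 ± 14.2 CPM. GPT2 and MTHFD2, enzymes of alanine and mitochondrial one-carbon metabolism, had log2 fold changes of 0.87 and 0.72. DDIT3, which encodes CHOP, was the lower member, with a log2 fold change of -0.44. PPP1R15A, ALDH1L2, PSPH, CBS and CEBPB did not pass, with log2 fold changes of -0.10, 0.14, 0.18, 0.09 and 0.10. PSPH passed in 10 of 18 alternatives (adjusted p = 0.017 to 0.147 over all), PPP1R15A in 3 (0.0363 to 0.89) and CEBPB in 2 (0.0345 to 0.503), none of them with a library left out. The list's median was 0.40 (camera adjusted p = 5.57e-28, and 0.0479 with an estimated correlation).

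Of 20 genes of the unfolded protein response, 12 were lower and 1 higher, with the same counts adjusted over the list alone (median -0.25, camera adjusted p = 1.22e-06; adjusted p = 0.231 with an estimated correlation). HSPA5, the chaperone BiP, fell from 1595 ± 52.2 to 1080 ± 49.8 CPM, and MANF, PDIA4 and HSP90B1 had log2 fold changes of -0.63, -0.56 and -0.41. XBP1 was the higher member (0.44). Of 20 heat shock genes, 11 were lower and 1 higher (14 and 2 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 7.27e-10, and 0.0479 with an estimated correlation). DNAJB1, an HSP40 co-chaperone, fell from 415 ± 4.07 to 226 ± 10.0 CPM, and CRYAB, a small heat shock protein, had a log2 fold change of -0.71. HSPA1A and HSPA1B, the inducible HSP70 genes, had log2 fold changes of -0.95 and -0.99. They are near-identical copies, so how their reads were divided is uncertain. CHORDC1 was the higher member (0.15), a call lost without H2O2 replicate 1, H2O2 replicate 2, arbutin replicate 1 or arbutin replicate 2 (edgeR adjusted p = 0.0986, 0.0950, 0.0780 and 0.0558). With quantile-normalised values the heat shock list did not pass (camera adjusted p = 0.0607).

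Mitotic genes were lower with arbutin. PLK1, a kinase of mitotic entry (ENSG00000166851, GRCh38 chromosome 16, 23677656 to 23690366, plus strand), fell from 154 ± 9.69 to 72.0 ± 2.72 CPM, a log2 fold change of -1.10 ± 0.0557 (SE, n = 3; edgeR adjusted p = 1.78e-06). CCNB1, cyclin B1, fell from 230 ± 19.4 to 102 ± 5.90 CPM, and KIF20A and CCNB2 had log2 fold changes of -1.05 and -0.94. In all, 25 of 30 mitotic genes were lower and none was higher (26 lower adjusted over the list alone), with a median of -0.69 (camera adjusted p = 2.16e-51, and 0.0455 with an estimated correlation). The 5 that did not pass were ASPM, FOXM1, CENPF, CENPE and MKI67, which encodes Ki-67. MKI67 stood at 304 ± 0.848 CPM with H2O2 and 323 ± 15.9 CPM with arbutin. Without arbutin replicate 3 MKI67 and ASPM passed as higher (edgeR adjusted p = 0.0337 and 0.0313), MKI67 also with FPKM of at least 5 required (0.046) and among protein-coding genes only (0.049), and FOXM1 passed as lower in 3 of the limma fits (0.0222 to 0.0332). Genes of DNA replication went both ways, with 7 of 35 higher and 12 lower (7 and 13 adjusted over the list alone; median -0.08, camera adjusted p = 0.0867). PRIM1, a primase subunit, fell (log2 fold change -0.71), and CCNE2, cyclin E2, rose (0.56). That list passed without the low-count filter (camera adjusted p = 0.0122). Of 31 DNA repair genes, 6 were higher, among them XRCC2 (0.69), and 9 lower, among them XRCC4 (-0.64), with the same counts adjusted over the list alone (camera adjusted p = 0.871).

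Of 29 p53 targets, 6 were higher and 8 lower (8 and 10 adjusted over the list alone). The list did not pass camera (adjusted p = 0.871), and its median (0.04) and mean (-0.01) had opposite signs. TNFRSF10B, a death receptor, and AEN rose, with log2 fold changes of 0.49 and 0.43, and GADD45A and PLK2 fell (-0.29 and -0.28). MDM2 rose from 53.2 ± 6.16 to 72.5 ± 1.24 CPM. CDKN1A, which encodes p21, did not pass (0.17, adjusted p = 0.0504), nor did GDF15 (-0.89, adjusted p = 0.0878). CDKN1A passed in 8 of 18 alternatives (adjusted p = 0.00596 to 0.197 over all), among them those without H2O2 replicate 3 and without arbutin replicate 2. Of 28 apoptosis regulators, 7 were higher and 4 lower, with the same counts adjusted over the list alone. CASP2 and XIAP rose (0.47 and 0.43). BIRC5, BAD, FADD and CASP6 were the lower members (-0.49, -0.29, -0.29 and -0.43). That list's camera direction was up and its median -0.01 (adjusted p = 0.871). BAX had a log2 fold change of -0.21, and BCL2 did not pass (-0.30, adjusted p = 0.191). The BAX call was lost without H2O2 replicate 1, H2O2 replicate 2, arbutin replicate 1 or arbutin replicate 2 (edgeR adjusted p = 0.105, 0.0938, 0.0859 and 0.104). The CASP6 call was lost without any library except arbutin replicate 3 (edgeR adjusted p = 0.0839 to 0.167).

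Genes of cholesterol synthesis fell together, with 23 of 24 tested genes lower and none higher, with the same counts adjusted over the list alone. HMGCS1, which makes HMG-CoA (ENSG00000112972, GRCh38 chromosome 5, 43287470 to 43313512, minus strand), fell from 162 ± 4.54 to 88.0 ± 2.54 CPM, a log2 fold change of -0.88 ± 0.0450 (SE, n = 3; edgeR adjusted p = 1.78e-06). INSIG1, a sterol-responsive regulator, had a log2 fold change of -0.88, and MSMO1 and IDI1, enzymes of the pathway, of -0.63 and -0.64. SREBF2, the transcription factor of the pathway, did not pass (-0.05). The list's median was -0.47 (camera adjusted p = 1.29e-26, and 0.0411 with an estimated correlation).

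Of 36 nuclear genes of oxidative phosphorylation, 28 were lower and none higher (31 lower adjusted over the list alone), with a median of -0.23 (camera adjusted p = 6.57e-09; adjusted p = 0.371 with an estimated correlation). ATP5F1C, of the ATP synthase, had a log2 fold change of -0.33. The 13 mRNAs encoded in the mitochondrial genome went both ways. MT-CO1 (0.30), MT-ND5, MT-ND6 and MT-ND4L were higher and MT-ND3 (-0.27) and MT-ATP8 lower, with the same counts adjusted over the list alone. That list had a median of -0.06, a mean of 0.01 and a camera adjusted p of 0.911. The MT-ND5 call was lost without H2O2 replicate 1, arbutin replicate 1 or arbutin replicate 2 (edgeR adjusted p = 0.0600, 0.0505 and 0.0571). The MT-ND6 call was lost without any library except the third replicate of each group (0.0604 to 0.0806), that of MT-ND4L without any library except arbutin replicate 3 (0.0631 to 0.164), and that of MT-ATP8 without any library except arbutin replicate 2 (0.0501 to 0.129). The share of mitochondrial ribosomal RNA differed between the same groups, as given above. Of 21 glycolysis genes, 12 were lower and none higher (14 lower adjusted over the list alone), with a median of -0.15 (camera adjusted p = 6.26e-06; adjusted p = 0.371 with an estimated correlation). SLC2A1, the glucose transporter GLUT1, fell from 309 ± 21.2 to 202 ± 15.2 CPM and PFKFB3 had a log2 fold change of -0.48. Of 51 ribosomal protein genes, 19 were lower and none higher (29 lower adjusted over the list alone). Their median was -0.14 (camera adjusted p = 1.55e-05; adjusted p = 0.615 with an estimated correlation), with RPS15 at -0.25. With quantile-normalised values the glycolysis and ribosomal protein lists did not pass (camera adjusted p = 0.0527 and 0.144), nor did the ribosomal protein list by fry's directional test (adjusted p = 0.111).

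**Figure D3:**
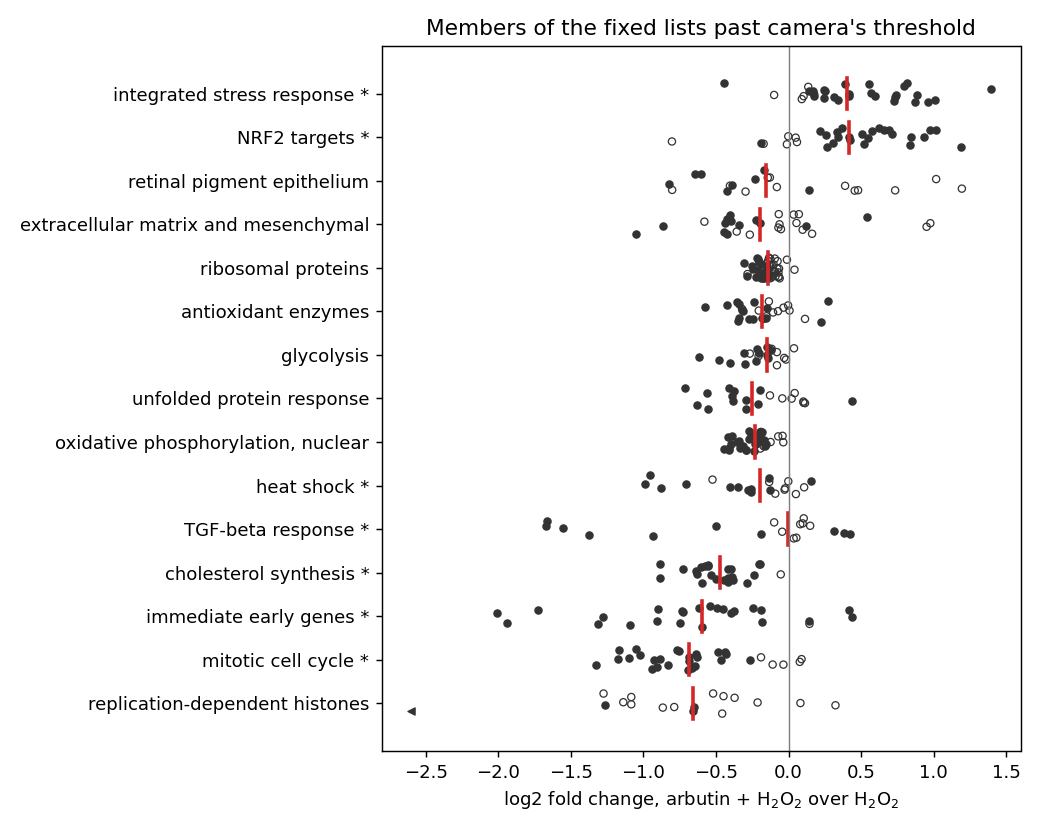
Log2 fold change of arbutin plus H2O2 over H2O2 (x axis) for each tested member of the 15 fixed lists past camera's threshold (y axis). Filled points passed edgeR's test, open points did not, the red line is the list's median, a star marks the 7 lists that also passed with an estimated correlation, and 1 histone gene beyond the axis is drawn as a triangle at its edge; mitotic, immediate early and cholesterol synthesis genes lie mostly left of 0.

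Of 20 retinal pigment epithelium genes, 7 were lower, 1 was higher and 12 did not pass (8 lower and 1 higher adjusted over the list alone). The list's median was -0.16 and its mean -0.04 (camera adjusted p = 0.000918, and 0.0742 with an estimated correlation). SOX9, MITF and OTX2, transcription factors of the pigment epithelium, had log2 fold changes of -0.82, -0.64 and -0.60, and KRT18 fell from 903 ± 33.0 to 674 ± 29.6 CPM. ITGAV was the higher member (0.14), a call lost without any library except arbutin replicate 1 (edgeR adjusted p = 0.05 to 0.191). Of 27 extracellular matrix and mesenchymal genes, 11 were lower and 2 higher (12 and 3 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.000107; adjusted p = 0.371 with an estimated correlation, and 0.0533 with quantile-normalised values). THBS1, thrombospondin 1, and SNAI1, a repressor of epithelial genes, had log2 fold changes of -0.86 and -1.05. ZEB1 (0.54) and COL4A1 (0.12) were the higher members, the latter lost without any library except arbutin replicate 3 (edgeR adjusted p = 0.0572 to 0.106).

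Of 18 TGF-beta response genes, 7 were lower and 3 higher, with the same counts adjusted over the list alone (camera adjusted p = 7.90e-07, and 0.0455 with an estimated correlation). The median was -0.004 and the mean -0.36. ID1, ID2 and ID3, inhibitors of helix-loop-helix factors that respond to bone morphogenetic proteins, had log2 fold changes of -1.55, -1.66 and -1.67. BHLHE40 fell from 148 ± 11.2 to 77.3 ± 2.97 CPM. SKI, PMEPA1 and SMURF2 were higher (0.42, 0.38 and 0.31). In the limma fits of log2 FPKM values the list did not pass (camera adjusted p = 0.280 to 0.312).

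Of 26 tested NF-kB and inflammation genes, 8 were higher and 7 lower, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.373; its median of -0.06 and mean of -0.03 were below 0 while camera's direction was up). TRAF1 and the NF-kB subunit genes RELB, NFKB1 and NFKB2 rose, with log2 fold changes of 0.625, 0.50, 0.42 and 0.40. IL6, at 5.13 ± 1.27 CPM with H2O2 and 3.04 ± 0.697 CPM with arbutin, was lower (edgeR adjusted p = 0.0296), a call lost without H2O2 replicate 1, H2O2 replicate 2, arbutin replicate 1 or arbutin replicate 2 (0.0982, 0.128, 0.0612 and 0.110). CXCL8 did not pass (-0.16, adjusted p = 0.0888), but passed in 4 of 18 alternatives (0.0098 to 0.534 over all), among them that without arbutin replicate 3 (edgeR adjusted p = 0.0098). Of 20 secreted senescence factors, 6 were higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.512, direction up with a median of -0.19). FGF2 rose (0.63) and PLAU fell (-1.87). Of 21 interferon response genes, 5 were lower, among them IFIT1 (-1.40), BST2, OAS1 and IFI6, and none higher, with the same counts adjusted over the list alone (camera adjusted p = 0.110, and 0.0341 without the low-count filter). IFI6 lost its call without H2O2 replicate 2 (edgeR adjusted p = 0.0677), and BST2 and OAS1 without any library except H2O2 replicate 3 (0.0591 to 0.110 and 0.0792 to 0.150).

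Of 18 ferroptosis regulators, 7 were higher and 3 lower, with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.0719). CHAC1, which degrades glutathione, rose from 17.7 ± 2.71 to 46.6 ± 3.11 CPM and TFRC, the transferrin receptor, from 359 ± 30.6 to 510 ± 19.1 CPM. HSPB1, VDAC3 and STEAP3 were lower (-0.40, -0.32 and -0.13), the last of them lost without each library in turn (edgeR adjusted p = 0.0761 to 0.141). The list passed without H2O2 replicate 1 (camera adjusted p = 0.0385), without arbutin replicate 1 (0.0486), with DESeq2 (0.0491) and with the trend on gene length removed (0.0246). Of 20 hypoxia response genes, 8 were lower and 2 higher (9 and 2 adjusted over the list alone; median -0.05, camera adjusted p = 0.0621). ADM fell from 142 ± 11.1 to 95.7 ± 4.83 CPM, and VEGFA and LOX were higher (0.37 and 0.23). That list passed without H2O2 replicate 1 (camera adjusted p = 0.0356), without H2O2 replicate 2 (0.0207), without the low-count filter (0.0341) and with the length trend removed (0.0348). Of 30 autophagy and lysosome genes, 6 were higher, such as MAP1LC3B (0.44), and 11 lower, such as NEU1 (-0.37; 6 and 12 adjusted over the list alone; camera adjusted p = 0.871).

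Of 12 melanin pigment genes, MYO5A was higher (0.39) and RAB38 (-0.43) and GPR143 (-0.18) lower, with the same counts adjusted over the list alone (camera adjusted p = 0.871). The GPR143 call was lost without H2O2 replicate 1, arbutin replicate 2 or arbutin replicate 3 (edgeR adjusted p = 0.102, 0.0865 and 0.0644). TYR, the rate-limiting enzyme of melanin synthesis, had 4 counts in H2O2 replicate 1 and 0 in the other libraries and was not tested. None of 9 photoreceptor genes passed (camera adjusted p = 0.911), although ROM1 passed as lower in 4 of the limma fits (adjusted p = 0.0281 to 0.0489). Of 6 immune cell genes ITGAM was higher (0.56), with the same count adjusted over the list alone (camera adjusted p = 0.871), and CD68 passed as lower in 4 of the limma fits only (adjusted p = 0.00886 to 0.0336). Of 10 endothelial genes ROBO4 passed (-0.22, from 29.3 ± 1.24 to 25.1 ± 1.10 CPM), and none adjusted over the list alone (camera adjusted p = 0.911). The ROBO4 call was lost without H2O2 replicate 1, H2O2 replicate 2, arbutin replicate 2 or arbutin replicate 3 (edgeR adjusted p = 0.0690, 0.0921, 0.0705 and 0.0836). Of 14 noncoding nuclear RNAs, SNHG1, GAS5, NEAT1 and SNHG12 were higher (0.45, 0.40, 0.32 and 0.17) and RMRP and RN7SK lower (5 higher and 2 lower adjusted over the list alone). That list's median was 0.0005, its mean -0.36 and camera's direction up (adjusted p = 0.245, and 0.0440 without arbutin replicate 1). SNHG12 lost its call without any library except arbutin replicate 1 (edgeR adjusted p = 0.0717 to 0.110), RN7SK without any except H2O2 replicate 3 (0.05 to 0.105) and RMRP without H2O2 replicate 2 (0.0822).

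Of 17 tested replication-dependent histone genes, whose typical mRNAs lack a poly(A) tail, H3C3, H2BC4, H4C8 and H2AC6 were lower and none higher (2 lower adjusted over the list alone). The list's median was -0.66, also with H3C3 at its bound (camera adjusted p = 0.0229, and 0.208 with an estimated correlation). With DESeq2 the camera adjusted p was 0.0557, and with the trend on gene length or GC content removed 0.114 and 0.0869. H4C8 and H2AC6 are also annotated with transcripts of the nonsense-mediated decay type, so their counts may include other transcripts. The 4 lower genes had under 4 CPM. H4C8 lost its call without each library in turn (edgeR adjusted p = 0.0526 to 0.168), H2AC6 without any library except arbutin replicate 3 (0.0652 to 0.147) and H2BC4 without H2O2 replicate 1, H2O2 replicate 2, arbutin replicate 1 or arbutin replicate 2 (0.0871, 0.0876, 0.0625 and 0.0812).

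Among called genes with a symbol whose groups did not overlap, most of the 10 largest fold changes in each direction belonged to genes near the detection limit. SLC6A3, the dopamine transporter, had 0 counts in the H2O2 group and 66 in the arbutin group, 22.0-fold higher against a floor of 3 counts over the group. On the same basis ASS1, argininosuccinate synthase, was 16-fold, HEXD-IT1 12.7-fold and HDAC1P2 12.4-fold higher. H3C3 and NOL4, with 0 counts in the arbutin group, were 21.0-fold and 19.6-fold lower. These values leave out counting error and the spread between libraries, so the true folds may be smaller. RPLP1P13, a pseudogene, had 42 counts with H2O2 and 2 with arbutin, a ratio of 21.0 with a counting interval of 5.45 to 179. The other higher genes were CATSPERD, SCN4A, LINC00547, CACNA1A, ARNTL2-AS1 and ITIH4. The other lower ones were RMRP, PTGES3L-AARSD1, LINC01122, IL22RA2, DDX25, GATA3 and LINC02606. Of the 20 genes, 5 kept the call without each library in turn (SLC6A3, ASS1, CATSPERD, H3C3 and NOL4). Leaving out H2O2 replicates 1, 2 and 3 ended 11, 10 and 7 of the calls, and leaving out arbutin replicates 1, 2 and 3 ended 11, 6 and 9, with an edgeR adjusted p of up to 0.181. Pseudogenes, histone genes with close copies and the antisense gene ARNTL2-AS1 cannot be told from related or opposite transcripts here. For PTGES3L-AARSD1, a read-through gene, H2O2 replicate 1 held 585 counts against 67 and 91 in the other H2O2 libraries, and its adjusted p was 0.0522 without that library.

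Among genes with a mean of at least 10 CPM, a limit chosen after the values were seen, the largest rises included CHAC1 (log2 fold change 1.40), AMIGO2, from 67.2 ± 7.29 to 149 ± 1.48 CPM, and SLC6A9, a glycine transporter, from 10.5 ± 1.39 to 22.6 ± 1.08 CPM. The largest falls included FOS, EGR1, the ID genes and CAVIN2, a caveola protein, from 57.5 ± 4.04 to 18.1 ± 1.45 CPM. SENP3-EIF4A1 (1.76), ZBED6 (1.39) and SPC24 (-1.64) overlap other genes, as do AMIGO2 and SLC6A9, and FBXW10 (1.55) and CDRT1 (1.54) are related copies. How reads were divided between these and their partners is uncertain. SRCAP, a chromatin remodeller, had a log2 fold change of 1.06. ZBED6 lost its call without H2O2 replicate 1 or arbutin replicate 2 (edgeR adjusted p = 0.05 and 0.0554). Annotated copies of 5.8S ribosomal RNA fell together, for example RNA5-8SN2 from 19.8 ± 3.62 to 5.67 ± 0.592 CPM, and their shared sequence makes each copy's value uncertain.

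Of the 27 readout genes fixed before the data were examined, 26 were tested, and 9 were higher and 12 lower. An exact two-sided permutation test of 3 against 3 libraries cannot give a p under 0.1, and 23 of the readouts had that smallest value. Camera with the preset correlation passed 15 of 33 lists, of which 7 passed with an estimated correlation (immediate early genes, NRF2 targets, integrated stress response, heat shock, mitotic cell cycle, cholesterol synthesis and TGF-beta response). The directional test of fry, which does not compare a list with other genes, also passed the lists of MAPK cascade kinases, MAPK output, DNA replication, hypoxia, ferroptosis and secreted senescence factors (adjusted p = 0.0182, 0.0238, 0.0397, 0.00854, 0.00513 and 0.0307). Among the terms that the file pairs with genes, camera passed 38 higher and 63 lower of 2224 GO terms, 2 and 10 of 306 KEGG pathways and 20 and 80 of 1371 Reactome pathways, and 0 of any kind with an estimated correlation.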

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

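Camera with length or GC trends removed was chosen after the data were seen. The counts of called genes stayed within 1.5 times of 3035 higher and 3232 lower with DESeq2, DESeq2's size factors, median scaling, no low-count filter, protein-coding genes only, an adjusted p under 0.10 and the limma fits of log2(FPKM + 1), with a median log2 fold change of all genes between -0.0599 and 0.00647. DESeq2 called 6823 genes and shared 98.4% of the main calls, its size factors in edgeR 97.6% and median scaling 98.2%. The share was 77.3% without the low-count filter, 86.8% for protein-coding genes, 81.5% with the replicate block and 81.9% to 84.9% in the limma fits. Leaving out 1 library kept 68.8% to 87.9% of the main calls, and FPKM of at least 5 kept 57.2%. A 2-fold minimum left 221 higher and 234 lower genes by construction, and FPKM of at least 5 in 3 libraries, which tests 6627 genes, left 1925 lower genes. Leaving out 1 library gave 2278 to 2970 higher and 2150 to 3018 lower genes, 15 to 18 lists, 16 to 22 readouts and 171 to 278 terms. The main test passed 15 of 33 lists, camera with the length trend removed 16, with the GC trend removed 14 and with an estimated correlation 7, and fry's mixed test, which asks for change in either direction, 31. The limma fit called 2442 genes higher and 3594 lower. Of its calls 40.5% were higher, against 48.4% in the main test and 51.2% after quantile normalisation. The limma fit passed 13 lists and 178 terms, and 9 lists and 125 terms after quantile normalisation. The main test passed 213 terms, and 0 with an estimated correlation. The cause of these differences was not tested. Of 207 named genes past the test, 161 kept the call without each library in turn and 159 in each alternative that tested them. Without the low-count filter 35 named calls were lost, and each other alternative, apart from leaving out a library and the replicate block, ended 1 to 8. Of the 20 largest changes, 5 kept the call without each library in turn.

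Several lists that did not pass in the main test or in the alternative changed direction, given here as the median log2 fold change with camera's direction opposite to that of the main test; the cause was not tested. For endothelial genes these were 0.314 with the length trend removed, 0.359 with DESeq2, 0.157 without the low-count filter, and 0.319 and 0.107 without H2O2 replicate 3 and arbutin replicate 1 (0.0475 to 0.495 over all libraries left out). For mitochondrially encoded genes they were -0.0785 with the GC trend removed, -0.0583 without the filter, and -0.0725, -0.1 and -0.0451 without H2O2 replicate 1, arbutin replicate 1 and arbutin replicate 2 (-0.1 to 0.000414 over all). Photoreceptor genes gave 0.255 with DESeq2 and -0.00812 without arbutin replicate 3 (-0.00812 to 0.35 over all). Melanin genes gave -0.0563 without the filter, -0.0969 with log2(FPKM + 1) and without the variance trend, -0.122 with the smaller pseudocount, -0.0658 with quantile normalisation, -0.103 with array weights and 0.17 without arbutin replicate 3 (0.0082 to 0.245 over all). Immune cell genes gave -0.435 without the filter. Autophagy genes gave -0.0338 at the stricter FPKM minimum, -0.0416 for protein-coding genes and 0.0384 with quantile normalisation. Apoptosis regulators gave -0.0748 without arbutin replicate 3 (-0.0748 to 0.0224 over all). Among named genes, MT-RNR2 had -0.122 with quantile normalisation, which gives equal values to equal ranks, and its rank was 1 in the H2O2 libraries and 2 in the arbutin libraries. PPP1R15A had 0.0104 with quantile normalisation and CENPF 0.0333 without arbutin replicate 3 (-0.128 to 0.0333 over all); neither gene passed the main test.

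The replicate numbers showed no pairing of the libraries over all tested genes. Deviations from the group mean correlated at -0.0073, -0.03 and 0.014 between libraries of the same number, and not every library correlated best with its own number. Counting noise of genes with few counts lowers such correlations, so a shared batch or order is not excluded. The groups did lie nearer each other at higher replicate numbers. Between libraries of the same number the chi-square per degree of freedom was 122, 90 and 52.7 for replicates 1 to 3. Mitochondrial ribosomal RNA took 2.42%, 2.8% and 2.97% of counts in H2O2 replicates 1 to 3. In arbutin replicates 1 to 3 it took 4.47%, 4.2% and 3.89%. A replicate block shifts both groups alike and does not remove such an order, whose cause was not tested. With the replicate block, 2596 genes were higher and 2598 lower, 16 lists passed, the ferroptosis list being the one gained (adjusted p = 0.0377), and 18 readouts and 185 terms passed. The block ended 27 named calls and added 1.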

Other observations

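Annotated terms past camera included amino acid transport and ribosome biogenesis, none of them with an estimated correlation. The term members named, the test on mitochondrial mRNAs, the medians with near-identical RNAs counted once or 5.8S ribosomal RNA added and the test on handling were chosen after the results were seen. Of 26 Reactome genes of amino acid transport across the plasma membrane, 13 were higher and 1 lower (camera adjusted p = 0.000165; adjusted p = 0.858 with an estimated correlation). Of these, SLC7A1 and SLC7A5 are also in the fixed list of the integrated stress response. SLC7A1, an importer of cationic amino acids, rose from 266 ± 19.9 to 468 ± 13.3 CPM (SD, n = 3; edgeR) and SLC7A5, which imports large neutral amino acids, from 703 ± 55.5 to 1170 ± 59.7 CPM. Of 75 KEGG genes of ribosome biogenesis, 34 were higher and 11 lower (adjusted p = 0.00358; 0.871 with an estimated correlation), with MDN1 rising from 44.5 ± 4.04 to 85.0 ± 5.54 CPM. Of 24 GO genes of histone methyltransferase complexes, 16 were higher and 5 lower (camera adjusted p = 0.000154, and 0.887 with an estimated correlation). Among them were KMT2D, KMT2C and KMT2B with log2 fold changes of 0.82, 0.71 and 0.50. No annotated term was weighed against gene length. Genes of the longest length decile had a median log2 fold change of 0.128, and those of the third -0.117.

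Of 87 GO genes of mitochondrial translational elongation, 47 were lower and 2 higher (camera adjusted p = 0.000154; 0.887 with an estimated correlation), MRPS10 and MRPS18B falling by 0.33 and 0.37 on the log2 scale. Of 41 genes of fatty acid beta-oxidation, 20 were lower and none higher (adjusted p = 0.0012; 0.887 with an estimated correlation), and CPT2, the inner carnitine palmitoyltransferase, had a log2 fold change of -0.74 ± 0.0883 (SE). Of 44 KEGG genes of branched-chain amino acid degradation, 24 were lower and 1 higher (adjusted p = 0.0086; 0.871 with an estimated correlation), including HMGCS1 (-0.88) and ACAT2 (-0.60), which are also in the fixed cholesterol synthesis list, and DLD (-0.37).

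The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many genes were higher (3035) and in 1 as many were lower (3232); a split has no direction of its own, and the larger count in either direction was at most 2 in the others. For lists, 1 split reached 15 and the highest other gave 13. For terms, 2 splits reached 213, the other being H2O2 replicates 1 and 2 with arbutin replicate 3, which gave 241. Camera's preset correlation passed lists and terms also where hardly any gene passed. Each other split, however, put 2 libraries of one treatment with 1 of the other. Part of the arbutin difference thus remained in it, and the rest widened the spread within its groups. Few called genes were therefore likely in these splits, and the lists and terms they passed cannot be called false. With an estimated correlation the real split gave 7 lists and each of the other splits 0, which the mixing also favours.

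The lower level of nuclear oxidative phosphorylation and ribosomal protein genes was weighed against bias by gene length and GC content, because genes of the third length decile had a median log2 fold change of -0.117 and those of the longest decile 0.128. After the trend with length was subtracted, the median of the 36 oxidative phosphorylation genes was -0.22 (bootstrap interval -0.288 to -0.182; -0.231 before), and after that with GC content -0.234 (-0.297 to -0.214). For the 51 ribosomal protein genes the values were -0.124 (-0.149 to -0.107; -0.14 before) and -0.154 (-0.17 to -0.133). Length was that implied by count and FPKM, with list medians of log2 11.69 and 11.67 against 12.14 outside the lists. It may differ from that of the expressed transcripts, so bias by transcript length stays open. The bootstrap treats genes of a list as independent, while their estimated correlations were 0.49 and 0.75, so its intervals are too narrow. Subtracting these trends left most of each median, which argues against a trend on that implied length or on GC content as the whole cause. The implied lengths of both lists lay near those outside the lists, so the subtraction says little about a bias by transcript length. A shared fall of each group under arbutin may remain, as a hypothesis, although neither list passed with an estimated correlation (adjusted p = 0.371 and 0.615).

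Both mitochondrial ribosomal RNAs were higher with arbutin, MT-RNR1 from 10100 ± 1050 to 17600 ± 1510 CPM (log2 fold change 0.80) and MT-RNR2 from 16900 ± 1880 to 24800 ± 1570 CPM (0.56). Carry-over of RNA without a poly(A) tail was taken to raise nuclear RNAs of that kind by at least 0.34 on the log2 scale. That bound is a chosen fraction of the mean of 0.68 of the 2 mitochondrial ribosomal RNAs. The class of 17 RNAs was assigned by annotation type and gene family, at a mean of at least 1 CPM. RMRP and RN7SK, lower as given above, were below that minimum and are not in it. Its snoRNAs other than SNORD3 had 0.031 to 0.958, and its histone, SNORD3 and RN7SL genes -1.51 to -0.222. The median of the 17 was -0.371 (bootstrap interval -0.656 to 0.142), with 2 higher (SNORD83A and SNORA73B), 5 lower and 4 above that bound. That interval treats near-identical copies as independent: with these counted once the median was -0.237 (-0.519 to 0.429), and with 5.8S ribosomal RNA, left out of the 17 and lower by 1.83 as the mean of its copies, that of 14 RNAs was -0.304 (-0.588 to 0.35), which still reaches the bound, so carry-over stays open although 5.8S ribosomal RNA went against it. A rise of mitochondrial RNA in all was taken to raise the 13 mRNAs by as much, and their median was -0.0564 (-0.101 to 0.224). That interval treats the mRNAs as independent, while their estimated correlation was 0.75, so it is too narrow. The median argues against such a rise only weakly. An effect of arbutin on these RNAs may be involved and was not tested, and with quantile normalisation MT-RNR2 changed sign (-0.122).

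The fall of immediate early genes was weighed against gene length and against handling of the dishes, since these genes respond within minutes to disturbance. After the trend with the length implied by count and FPKM was subtracted, the list's median was -0.583 (-0.596 before). Its bootstrap interval, -0.858 to -0.377, treats the genes as independent, while their estimated correlation was 0.11. The median argues against a trend on that length as the whole cause. The gap between the groups in the mean log2 CPM of FOS and EGR1 was 1.65, 5.3 times the larger range within a group (0.311). That mean fell with replicate number in the H2O2 group (6.62, 6.47 and 6.31) but not in the arbutin group (4.66, 4.53 and 4.62). Handling and arbutin cannot be told apart, because the dishes of a group may have been harvested together. Whether arbutin lowers the signal upstream of these genes stays an untested hypothesis.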
